A study of Mus musculus with 8 samples.

How the data were processed

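The labels describe RNA from mouse cartilage, isolated with TRIzol and a column kit and sequenced by a commercial provider. They place 8 samples in 4 groups of 2 by injury state and treatment, and groups were taken from the sample titles. The submitters' processing notes name STAR, Partek and DESeq2, with no version, and the genome build, by its names GRCm38 and mm10. They assign no role to these tools, and the counting method, the annotation and the filter on genes are not given in the sources used here.

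The authors deposited a gene table, described in its name as filtered features and filtered counts, with a column of gene symbols and 8 columns of values. Apart from the word counts in that name, no label or header states the unit of the deposited values. The values were looked at only to judge that unit. The column headings hold a number, written as a digit or a word, and L or R, with each of 4 numbers heading a column of either letter. No sample label holds a side or ties such a number to a sample, the sample descriptions are empty, and the table has no row that names a treatment or an injury. Beyond that look, all 8 value columns were left out of every step for this reason. Assigning them by column order, by side or by the level of any gene would have been a guess, and none was made.

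The comparisons fixed before the data were examined were 7 quasi-likelihood tests and 7 matching gene list tests over 4 groups, with alternatives for scaling, filtering, model, pairing and left-out samples. None could be run, and sequencing depth, replicate spread and duplicate libraries were not examined. The rule for named genes fixed at that time called for genes by adjusted p, the fixed single genes and list members by p. The parts that rest on p-values could not be applied. The genes named are those of the 27 fixed single genes, examples from the fixed lists and, where a list was incomplete, each member not listed. The members of 1 injury list, 6 of whose 11 genes were in the table and which holds 5 of the 15 list genes not found there, are not reported here. The examples were picked without reference to any measurement.

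What was computed, with Python 3.11.15, was the presence of each gene symbol among the 15295 rows. Symbols were matched exactly, case included, to gene names of the GENCODE M21 comprehensive annotation, whose GRCm38 build is the build named by the submitters' processing notes. Coordinates are 1-based and come from that annotation, not from the authors' files. A gene name with several entries was represented by its first entry. The 40 gene lists and the 27 single genes were fixed before the data were examined. A set of sex-linked genes fixed as a sample check was not used, since no value column was used. Matching to RefSeq symbols and synonyms and to the basic annotation were tried as alternatives.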

Results

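The series addressed how a CSF1-R inhibitor alters gene expression in mouse cartilage after the anterior cruciate ligament has been cut. CSF1-R is the receptor for the cytokines CSF1 and IL-34, on which macrophages and osteoclasts depend. Cutting the ligament (ACL transection, ACLT) destabilises the knee and is used to model post-traumatic osteoarthritis. The labels describe RNA sequencing of 8 cartilage samples in 4 groups of 2. The groups were uninjured or ACLT cartilage from mice given either the inhibitor at 40 mg/kg or a 0.5% sucrose placebo in the drinking water, with treatment lasting 7 days after the injury. The labels call the samples biological replicates.

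The gene table used here held 15295 rows, each with a distinct gene symbol, and 8 columns of values. The columns were headed by a number and the letter L or R, and each of 4 numbers occurred once with L and once with R. The labels do not say whether the columns that share a number come from 1 animal. The sample labels give only the injury state, the treatment and a replicate number of 1 or 2. They name no side, and nothing in them ties a number in a heading to an animal or to a replicate. No column could therefore be matched to a sample or to a group. None of the values was used, and no expression level, total count per sample, fold change or p-value is given. Of the 7 planned comparisons, which covered the injury effect under each treatment, the inhibitor effect in each joint state, their interaction and both averages, none was run.

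What could be described without the values was which genes the table lists, that is, which genes were retained in the features the authors kept. The filter they applied is not given in the sources used here. Whether it worked over all samples together, per group or per sample is therefore unknown, and the presence of a gene is not read as expression in any group. Of the listed symbols, 15060 (98.5%) matched a gene name in GENCODE M21, an annotation of the GRCm38 build, and 235 did not. The table listed 13551 of the 21991 protein-coding gene names in that annotation (61.6%). The matched symbols also included 671 pseudogenes of all classes, 97 immunoglobulin gene segments and 4 T cell receptor constant genes. From the mitochondrial genome it listed 15 of 37 genes, namely 13 protein-coding genes and 2 ribosomal RNA genes.

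The target of the treatment was listed. Csf1r (ENSMUSG00000024621.16) lies on chromosome 18 at 61100598 to 61132149 on the plus strand. Its ligands were listed as well, Csf1 on chromosome 3 at 107741048 to 107760469 and Il34 on chromosome 8 at 110741829 to 110805924, both on the minus strand. All 9 genes of the CSF1 receptor list were present. Besides Csf1r and its ligands, that list holds other receptor genes, such as Csf2ra and Kit, and Spi1, a transcription factor of myeloid cells. All 22 macrophage markers were listed, among them Adgre1, Cd68, Mrc1 and C1qa, as were all 12 monocyte markers. Of 15 osteoclast genes 14 were listed, including Acp5, the tartrate-resistant acid phosphatase, and Ctsk, a collagen-degrading protease, and Calcr was not.

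Cartilage genes were listed nearly in full, as were the genes of all 40 lists together (525 of 540, 97.2%). All 7 cartilage collagen genes were present, including Col2a1, the main fibrillar collagen of hyaline cartilage, on chromosome 15 at 97975602 to 98004695. Of 17 proteoglycan and matrix protein genes 16 were listed, among them Acan, which encodes aggrecan, on chromosome 7 at 79053483 to 79115099, and Comp. Matn1 was the gene of that list not found among the rows. The 10 superficial zone genes were all present, including Prg4, which encodes lubricin. So were the 14 genes of hypertrophic and mineralizing cartilage, including Col10a1. Of 13 chondrocyte regulators 12 were listed, including Sox9, and Gdf5 was not.

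Genes linked to joint injury were also listed, and 5 of the 6 lists of this kind are described. The other list was the least complete of all 40, with 6 of 11 genes present. The matrix-degrading enzymes numbered 18 of 19, with the collagenase Mmp13, the stromelysin Mmp3 and the aggrecanases Adamts4 and Adamts5 among them, and Mmp10 was not listed. All 10 protease inhibitors were present, including Timp1, as were all 20 inflammatory cytokine and chemokine genes, including Il6, Il1b, Tnf and Ccl2. The 12 NF-kB response genes and the 20 fibrosis genes, including Col1a1, Col3a1 and Postn, were listed without exception.

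Genes from lists for cells other than chondrocytes were listed too. Some of them, such as Thbs4, Fmod, Ibsp and Alpl, are also in the cartilage lists. All 20 skeletal muscle genes were present, including the muscle actin Acta1, as were all 15 neutrophil, 13 B and plasma cell, 12 adipocyte and 13 endothelial and perivascular genes. The same held for the 9 megakaryocyte and platelet, 10 tendon and ligament, 14 fibroblast and 9 nerve glia genes. Of 13 erythroid genes 12 were listed, of 13 osteoblast and osteocyte genes 11, of 14 T and NK cell genes 13, and of 9 mast cell and basophil genes 8. The genes not listed were Bglap3, Fgf23, Ncr1, Cma1 and Ahsp. Ahsp is also neither a gene name in the GENCODE M21 copy used here nor a symbol or synonym in the RefSeq table. The synonym search therefore did not cover it, and whether it is listed under another name was not examined. Presence in the table does not give the amount of any of these transcripts.

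Among the 12 lists of cell processes, every gene was listed for cell cycle, interferon response, antigen presentation, complement, immediate early genes, oxidative phosphorylation, the unfolded protein response, lysosome, BMP and TGF-beta signalling, Wnt signalling and cartilage growth factors. For glycolysis and hypoxia 15 of 16 genes were listed, without Ankrd37. Over all 40 lists, 525 of 540 distinct genes (97.2%) were present, and 30 lists were complete. All 27 genes chosen to be reported singly were among the rows.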

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

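No paired analysis was possible for the planned comparisons because no value column could be given a group or a replicate number of the labels. The headings form 4 pairs of L and R with a shared number. A fit of L against R within these pairs was not run, since the labels give neither letter a meaning. Without groups, every alternative planned for the comparisons was not run: other scalings, filters and models, fits on fewer groups, left-out samples and an estimated correlation for gene lists. How the expression results depend on processing and on depth therefore remains unknown. The alternatives that could be run concern gene names and were chosen after seeing the data. The number of listed symbols matched to an annotation was 15060 with GENCODE M21, 14776 with RefSeq symbols and 14833 with RefSeq symbols and synonyms. Allowing RefSeq synonyms left the number of list genes present at 525. The basic annotation left the number of protein-coding genes at 13551, but it comes from the same GENCODE release and is not an independent check.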
